A study of Mus musculus with 9 samples.

How the data were processed

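RNA was analysed from 3 populations of cells sorted by flow cytometry from the back skin of 3 mice, with 1 array per mouse and population. Per the labels' protocols, total RNA was isolated with a column kit, amplified with the WT-Ovation Pico system, labelled with biotin and hybridised to 1-colour arrays. The deposited values are log2 expression values per probe set, and the submitters' processing notes name RMA (robust multi-array average, a background correction, quantile normalization and probe summary). Its version, the software, and whether the 9 arrays were normalized together are not given in the sources used here. The range of the values (1.65 to 14.8) and the closeness of the quartiles (upper quartile 7.91 to 8.04) were checked against that scale. Amplification from small amounts of RNA and the quantile step can compress folds and hide a change shared by most genes, and RMA values carry no detection call, so background was judged from 81 olfactory receptor probe sets. No scanner files were used here.

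Probe sets were named from the platform annotation of the 45101 probe sets, of which 34958 had 1 gene symbol, 932 had several and 9211 had none. Of those with 1 symbol, 34754 were found in a RefSeq gene table (GRCm38.p6, used for names alone), and 0 symbols were updated. Probe sets with several symbols, and the 64 control probe sets, took no part in tests of genes. Each of 18194 genes was represented by its probe set with the highest mean over the 9 arrays; 9012 genes had several probe sets. Among 532 listed or named genes, 318 had several probe sets, and in 0 cases was another probe set called in the opposite direction to a called gene.

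Groups came from the labels, and the mouse number from the same labels. Same-numbered arrays come from the same mouse and are therefore paired. The deviations of arrays from their gate means correlated at -0.074 to 0.193 (mean 0.069) within a mouse and at -0.19 to 0.117 (mean -0.034) between mice. The 3 mice are separate animals. Differences between the 3 gates were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) with 1 coefficient per gate over all 9 arrays and no block for the mouse, no filter on dim genes, and Benjamini-Hochberg adjustment within each comparison. Genes were called at an adjusted p under 0.05. Values are group means ± SD, changes are on the log2 scale with the moderated standard error, and the total degrees of freedom were 9.49.

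Before the data were examined, the tests, the alternatives, 24 gene lists and the rule for the genes named in the text were fixed. The lists cover papilla and fibroblast genes, markers of other skin cell types, signalling pathways, proliferation, dissociation stress and patterning; 35 genes are in more than 1 list. Genes of the lists that had no probe set of their own are not analysed here. Lists were tested with limma's camera at its preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison, and again with a correlation estimated for each list. With the mouse as a random block, lists were tested with limma's cameraPR, a camera test run on the t-statistics of the fit. The genes named were, per comparison, those among the called genes with the same sign in all 3 mice that had the 8 largest rises and the 8 largest falls, the gate genes, and up to 4 members with the lowest p of each list described. Clone-type and predicted symbols were skipped. The alternatives were the mouse as a fixed or random block, leaving out each array, fitting the 6 arrays of a comparison alone, centring each array on its median, quantile normalization again, the mean of all probe sets of a gene or all probe sets tested singly, genes above the median gene only, a trend and robust variance, a 2-fold minimum, and the estimated list correlation.

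The test was checked on simulated data with the real mean and the moderated spread of each gene, in which 200 of 18194 genes were changed. For R3 against R2, 16% of 1.5-fold, 60% of 2-fold, 100% of 4-fold and 100% of 8-fold changes were recovered, and 9 of the 147 called genes were unchanged ones. Of 3 lists shifted in the simulation 3 were called, and of 20 unchanged lists 0 were called by camera. The genes were simulated independently, so this check does not cover lists whose genes are correlated. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.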

Results

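Expression was measured on 9 arrays of RNA from cells sorted out of the back skin of 3 neonatal mice, numbered 2, 4 and 5, at postnatal day 2. Each mouse gave 1 array for each of 3 gates. R1 held GFP-CD133- cells, the general dermal cell pool without dermal papilla cells. R2 held GFP-CD133+ cells and R3 held GFP+CD133+ cells, which the labels describe as dermal papilla cells of different hair types, zigzag for R2 and guard, awl and auchene for R3. The dermal papilla is the cluster of mesenchymal cells at the base of the hair follicle. CD133 is the protein of Prom1, and GFP is known from work on these mice as a reporter of Sox2. The values were log2 expression values, with array medians from 6.13 to 6.20. The 95th percentile of 81 olfactory receptor probe sets, used as a guide to background, lay between 5.29 and 6.07, so folds against levels in or under that range rest on dim signals. With 3 arrays per gate, the number of arrays limits the precision. Arrays of the same gate correlated across probe sets at 0.977 to 0.985, against 0.967 to 0.974 between R2 and R3, 0.962 to 0.968 between R1 and R2 and 0.951 to 0.959 between R1 and R3. Probe sets are not independent replicates. The difference between the 3' and 5' control probe sets of beta-actin, a sign of RNA quality, was 0.05 ± 0.01 in R1, 0.16 ± 0.06 in R2 and 0.15 ± 0.04 in R3 (log2, SD, n = 3), with each R1 array (0.04 to 0.07) under each R2 and R3 array (0.11 to 0.22). That of Gapdh was 2.85 ± 0.19, 2.68 ± 0.15 and 2.84 ± 0.17, and its arrays overlapped.

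**Figure D1:**
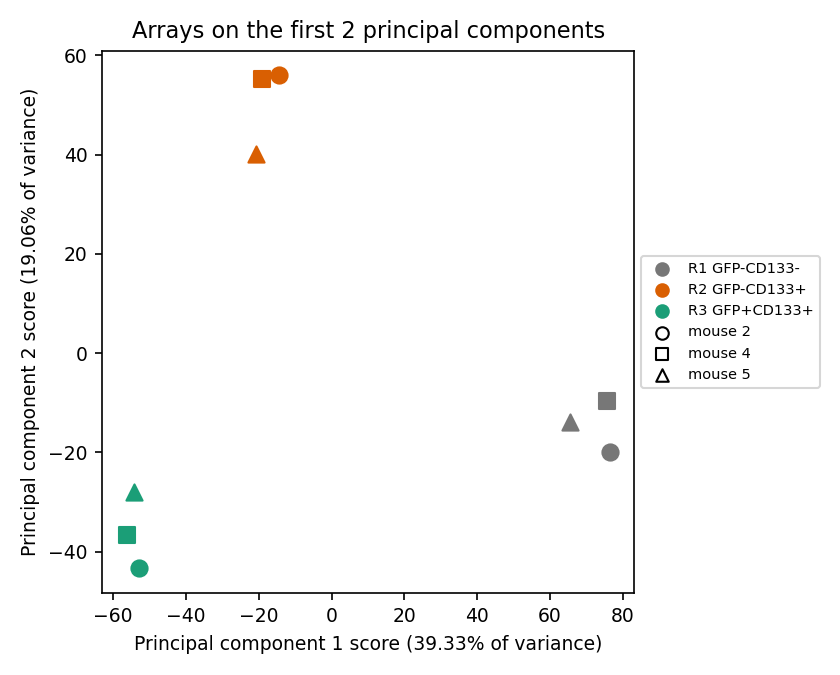
Scores of the 9 arrays on principal component 1 (x axis, 39.33% of variance) and principal component 2 (y axis, 19.06% of variance), with the gate as colour and the mouse as symbol. The 3 arrays of each gate lie together.

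Both genes behind the gates followed the sort, which checks the labels and is no finding between gates. Prom1 stood at 7.43 ± 0.36 in R1, 11.85 ± 0.04 in R2 and 10.32 ± 0.19 in R3 (log2 value, SD, n = 3). Sox2 stood at 4.19 ± 0.34 in R1, 7.08 ± 0.61 in R2 and 10.66 ± 0.12 in R3. Sox2 was thus 12-fold higher in R3 than in R2 (limma adjusted p = 0.000104), while in R2, gated as GFP-negative, it exceeded R1 by 2.90 on the log2 scale (adjusted p = 0.000192). Prom1 was 2.90-fold lower in R3 than in R2 (adjusted p = 0.00112).

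**Figure D2:**
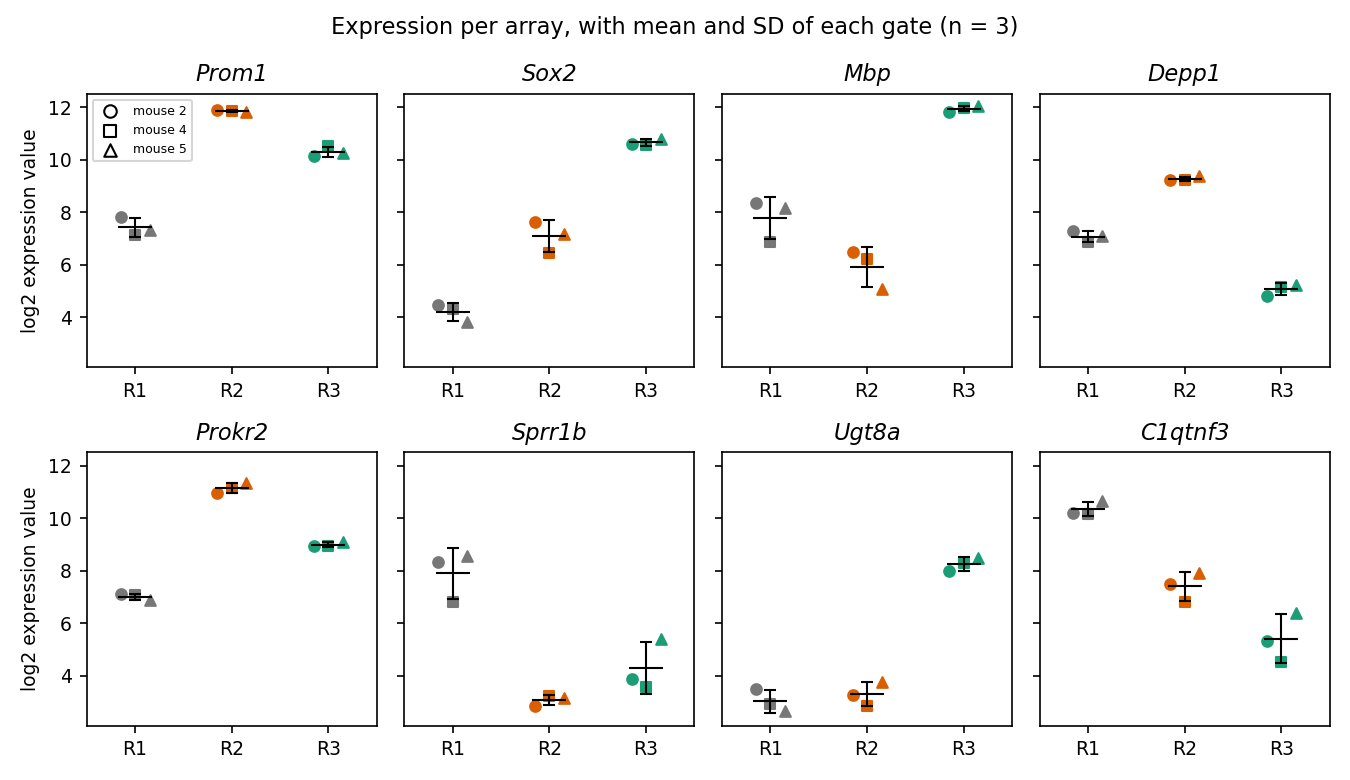
Log2 expression values (y axis) of the gate genes Prom1 and Sox2 and of the gene with the largest rise and the largest fall in each comparison, by gate (x axis), with 1 symbol per mouse and bars for the mean and SD of 3 arrays. Mbp averages 11.95 in R3 and 5.92 in R2, and Depp1 averages 5.07 in R3 and 9.28 in R2.

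The comparison of R3 with R2 asks how the 2 dermal papilla populations differ. The largest rises in R3 among the named genes were those of Mbp, Bcas1, Ugt8a and Mal, known from myelin or myelin-forming cells. Mbp, which encodes myelin basic protein, was 65.4-fold higher in R3 than in R2 (log2 change 6.03, standard error 0.43, n = 3 per gate, adjusted p = 5.28e-05). Bcas1, known from myelin-forming cells, was 37.1-fold higher, Ugt8a, an enzyme of myelin galactolipid synthesis, 31.5-fold, and Mal, a myelin proteolipid, 31-fold. Itgb8, an integrin subunit, was 23.3-fold higher, and the neural adhesion gene Chl1, the fatty acid binding protein gene Fabp7 and Nkain2 were 18.6-fold, 18.2-fold and 17.2-fold higher. In R2 all of these genes but Chl1 (6.38) stood in or under the range of the background guide, so their folds rest on dim signals. The named genes with the largest falls included several known from endothelium.

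Depp1 was 18.5-fold lower in R3 than in R2 (log2 change -4.21, standard error 0.16, adjusted p = 1.42e-06). Adgrf5, an adhesion receptor of endothelium, was 16.8-fold lower, and Mmrn1 (multimerin), Emcn (endomucin) and Myct1 were 15.7-fold, 14.6-fold and 14.2-fold lower. The endothelial transcription factor Sox17 and the cytokine receptor subunit Csf2rb were each 12.9-fold lower. Hoxd13, a patterning gene of distal limb and genital tissue, was 13.3-fold lower with a wide error (log2 change -3.73, standard error 0.71, adjusted p = 0.016). Its adjusted p was 0.069 without R2 replicate 2, 0.0552 without R2 replicate 4, 0.0597 without R3 replicate 4 and 0.0514 without R3 replicate 5, within a range of 0.00108 to 0.069 over the alternatives. The R3 levels of all these lower genes, from 4.14 (Myct1) to 5.65 (Sox17), lay in or under the range of the background guide.

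The marker lists showed these directions as groups. Of 11 measured Schwann and glial genes, 9 rose in R3 against R2 (10 adjusted over the list alone), with a median log2 change of 1.97. Cdh19, a cadherin of Schwann cell precursors, was 14.8-fold higher, and Erbb3, the neuregulin receptor, 7.98-fold. Of 16 measured endothelial genes, 14 fell (16 adjusted over the list alone), with a median log2 change of -2.22. The VEGF receptor gene Kdr was 3.95-fold lower, the tight junction gene Cldn5 4.73-fold and Robo4 8.72-fold. Both lists were called by camera (adjusted p = 4.04e-17 and 1.11e-24) and stayed called with an estimated correlation (adjusted p = 0.00341 for each). Across all genes 5.03% were called in this comparison.

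The dermal papilla list was also higher in R3, with 8 of 31 measured genes up and 2 down (12 and 3 adjusted over the list alone) and a median log2 change of 0.32 (camera adjusted p = 1.35e-05, and 0.0282 with an estimated correlation). Rspo2, a secreted enhancer of Wnt signalling, was 10.3-fold higher, the BMP and Wnt antagonist Sostdc1 4.14-fold, the hedgehog-binding protein gene Hhip 3.53-fold and the proteoglycan gene Vcan 2.32-fold. The count of higher genes was 5 without R2 replicate 4, R3 replicate 2 or R3 replicate 4, and that of lower genes was 1 without R2 replicate 4, R2 replicate 5, R3 replicate 2 or R3 replicate 4. In the same comparison, glial genes rose and endothelial genes fell.

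Dermal fibroblast and matrix genes were lower in R3, with 7 of 28 down (14 adjusted over the list alone) and a median of -0.38 (camera adjusted p = 2.45e-05, and 0.0371 with an estimated correlation). Dpt was 2.18-fold lower, Lum 1.89-fold and Thy1 1.75-fold. The count was 3 without R2 replicate 2 or R3 replicate 4, and 4 without R2 replicate 5 or R3 replicate 2. Notch signalling genes were lower too, with 11 of 23 down and 1 up (14 and 1 adjusted over the list alone) and a median of -0.62 (camera adjusted p = 4.15e-07, and 0.0235 with an estimated correlation). Notch4, a receptor known from endothelium, was 3.50-fold lower, the target Heyl 3.11-fold and the ligand Dll1 2.36-fold, beside the fall of 14 of 16 endothelial genes. The count of lower Notch genes was 4 without R2 replicate 2, R2 replicate 4 or R3 replicate 2, and 6 without R2 replicate 5 or R3 replicate 4; the single higher gene was not called without R2 replicate 2, R2 replicate 5, R3 replicate 2 or R3 replicate 4.

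Of 8 measured adipocyte genes 3 were lower in R3 (3 adjusted over the list alone; camera adjusted p = 0.00992, but adjusted p = 0.153 with an estimated correlation). These were Fabp4 (2.32-fold), Cd36 (3.40-fold) and Pparg (2.68-fold), of which Fabp4 and Cd36 are also known from capillary endothelium. The HOX and homeobox list had 8 of 50 genes lower and 2 higher (16 and 3 adjusted over the list alone; camera adjusted p = 0.000189, but adjusted p = 0.153 with an estimated correlation). The HOX call was also lost among genes above the median gene (camera adjusted p = 0.182). Meox2 was 9.93-fold lower, Hoxd10 6.30-fold, Meox1 5.66-fold and Hoxb4 1.92-fold. The count of lower genes was 5 without R3 replicate 4, and that of higher genes was 1 without R2 replicate 2, R2 replicate 4, R3 replicate 4 or R3 replicate 5.

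Cell cycle genes shifted lower in R3 as a set (median -0.38, camera adjusted p = 7.01e-07), a call that was lost with an estimated correlation (adjusted p = 0.108). Of its 30 genes 2 were called lower (7 adjusted over the list alone) and 17 were lower at an unadjusted p under 0.05. With limma the count was 1 without R2 replicate 5 or R3 replicate 2, and 0 without R2 replicate 2 or R2 replicate 4. The pericyte and smooth muscle list was called lower (camera adjusted p = 0.0117, but adjusted p = 0.125 with an estimated correlation), with the potassium channel gene Kcnj8 2.21-fold lower. The keratinocyte list was called higher (median 0.15, camera adjusted p = 0.0171, but adjusted p = 0.394 with an estimated correlation) although limma called 0 of its 22 genes, with 5 higher at an unadjusted p under 0.05. That call was lost without R2 replicate 4 (adjusted p = 0.0579), R3 replicate 2 (adjusted p = 0.115) or R3 replicate 5 (adjusted p = 0.182). It was also lost with the mouse as a random effect and cameraPR (adjusted p = 0.0547). The adjusted p of the list ranged from 5.33e-05 to 0.394 over its alternatives. Without R3 replicate 4, limma called 1 gene of the list.

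The other 14 lists were not called (camera adjusted p from 0.0691 to 0.936), although single members stood far apart. In the IGF list 2 of 18 genes rose and 2 fell (4 and 5 adjusted over the list alone). Pappa2, a protease that cleaves IGF-binding proteins, was 10.5-fold higher in R3 and Igfbp5 2.80-fold higher, while Igf2 was 2.04-fold and Igf1 2.28-fold lower. In the integrin list 3 of 18 rose and 2 fell (4 and 2 adjusted over the list alone), among them Itga9 at 3-fold and Itga6 at 2.02-fold higher and Itga8 at 2.11-fold lower. In the hedgehog list 3 of 17 rose and 2 fell (3 and 5 adjusted over the list alone). The ligand gene Dhh, known from Schwann cells, was 5.52-fold higher, and the receptor component genes Cdon and Gas1 were 3.54-fold and 2.22-fold lower; 2 rose without R2 replicate 4, R2 replicate 5, R3 replicate 4 or R3 replicate 5, and 4 fell without R2 replicate 5. The BMP list missed the threshold (adjusted p = 0.0691), within a range of 0.00918 to 0.371 over its alternatives. It passed with the mouse as a fixed block (camera adjusted p = 0.0295) and without R2 replicate 2 (0.0174). The list also passed after quantile normalization again (0.024), among genes above the median gene (0.00918) and with a trend and robust variance (0.039). With the mouse as a random effect and cameraPR its adjusted p was 0.0313. Its antagonist Fst was 2.41-fold higher in R3. The leukocyte list was called without R2 replicate 2 (adjusted p = 0.0433, range 0.0433 to 0.86 over its alternatives). With the mouse as a random effect and cameraPR, the integrin list (adjusted p = 0.0127, range 0.0127 to 0.153) and the TGF-beta list (adjusted p = 0.0425, range 0.0425 to 0.843) were called. Integrins were also called after quantile normalization again (camera adjusted p = 0.0427).

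In all, limma called 915 of 18194 genes between R3 and R2, 358 higher and 557 lower in R3, and each had the same sign in all 3 mice. The arrays of the gates did not overlap for 22.7% of genes, where chance gives 10%. The count was 596 without R2 replicate 2, 582 without R2 replicate 4 and 592 without R3 replicate 4. In simulated data with 200 changed genes, 1.5-fold changes were recovered in 16% of cases, 2-fold changes in 60% and 4-fold changes in 100%. With 147 genes called there against 915 here, the adjusted threshold was stricter there. These rates therefore need not hold for the real data.

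The comparison of R2 with R1 asks what sets the GFP-negative papilla population apart from the dermal pool. Prokr2, a prokineticin receptor gene, was 17.7-fold higher in R2 (log2 change 4.14, standard error 0.14, n = 3 per gate, adjusted p = 1.68e-06). Clic5, the glutamate transporter gene Slc1a1 and the metalloprotease gene Adamts20 were 16.2-fold, 15.4-fold and 15.1-fold higher. Clstn2, Sox2ot, Kcnj3 and Spock1 were 12.2-fold to 13.3-fold higher; Sox2ot overlaps Sox2 in the genome. Epithelial genes gave most of the largest falls: the cornified envelope gene Sprr1b was 28.3-fold lower (log2 change -4.82, standard error 0.53, adjusted p = 0.000367), Prr9 19.8-fold, Krt1 19.1-fold, the inner root sheath keratins Krt25 and Krt27 14.5-fold and 14.4-fold, and the desmosomal gene Dsg1a 13.7-fold. Ckmt1 and the leukocyte gene Cd69 were 13.2-fold and 13.1-fold lower.

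The beta-actin 3' to 5' difference lay higher in R2 than in R1 (mean 0.16 against 0.05), beside each gene group of this comparison. That of Gapdh averaged 2.68 in R2 and 2.85 in R1, with overlapping arrays. Dermal papilla genes rose in R2, with 19 of 31 higher and 1 lower (22 and 1 adjusted over the list alone) and a median of 0.96 (camera adjusted p = 3.33e-15, and 0.00627 with an estimated correlation). Corin, a papilla protease, was 11.5-fold higher, Inhba, an activin subunit, 8.42-fold and Rspo3 2.31-fold. The single lower gene was called lower with all arrays and without R1 replicate 4, and not without any other array of these gates. Endothelial genes rose as well, in 14 of 16 cases (15 adjusted over the list alone) with a median of 1.31 (camera adjusted p = 4.45e-14, and 0.0171 with an estimated correlation). Flt1 was 6.35-fold higher and Kdr 5.21-fold. Notch genes were higher in 11 of 23 cases and lower in 2 (13 and 2 adjusted over the list alone; camera adjusted p = 4.36e-07, and 0.0223 with an estimated correlation). The ligand Dll1 was 7.70-fold and the effectors Hey2 and Hey1 6.46-fold and 4.16-fold higher. The count of lower Notch genes was 1 without R1 replicate 2, R1 replicate 4, R2 replicate 2, R2 replicate 4 or R2 replicate 5.

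Keratinocyte, leukocyte and fibroblast genes were lower in R2. Of 22 keratinocyte genes 19 fell (20 adjusted over the list alone), with a median of -2.66 (camera adjusted p = 9.06e-20, and 0.0279 with an estimated correlation); Krt17 was 11.4-fold, Krt5 10.4-fold and Krt14 9.44-fold lower. Of 23 leukocyte genes 11 fell (12 adjusted over the list alone). The list was called by camera (adjusted p = 4.35e-08, and 0.0497 with an estimated correlation). Among its lower genes were the mast cell genes Mcpt4 (10.5-fold), Ms4a2 (9.25-fold) and Tpsb2 (7.53-fold). Of 28 fibroblast and matrix genes 14 fell and 1 rose (18 and 1 adjusted over the list alone; camera adjusted p = 4.95e-07, and 0.0223 with an estimated correlation), with Dpp4 5.38-fold, Lum 3.01-fold and Dcn 2.90-fold lower.

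The other 8 called lists lost the call with an estimated correlation. Melanocyte, glial, cell cycle and skeletal muscle genes were lower as sets (adjusted p = 0.000198, 0.000519, 2.13e-06 and 0.0158, and with an estimated correlation adjusted p = 0.125, 0.0597, 0.0822 and 0.0979). BMP, immediate early, axon guidance and HOX genes were higher as sets (adjusted p = 0.00665, 0.0152, 0.00516 and 9.63e-06, and with an estimated correlation adjusted p = 0.215, 0.125, 0.0597 and 0.0822). The skeletal muscle call was also lost without R1 replicate 2 (adjusted p = 0.064, range 0.00641 to 0.0979 over its alternatives). Among genes above the median gene the BMP and immediate early calls were lost (camera adjusted p = 0.0697 and 0.104). Bmp7 was 5.81-fold, the ephrin receptor gene Ephb1 5.18-fold and Hoxd10 5.05-fold higher, while the melanin synthesis gene Dct was 5.33-fold and Erbb3 5.51-fold lower. The 10 remaining lists had adjusted p from 0.0566 to 0.941. The lowest of these, adipocytes, passed without R2 replicate 2 (adjusted p = 0.00805, range 0.00805 to 0.24 over its alternatives). It also passed with a trend and robust variance (camera adjusted p = 0.0495).

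In all, limma called 2375 genes between R2 and R1, 1254 higher and 1121 lower in R2, of which 2374 had the same sign in all 3 mice. The arrays did not overlap for 30.8% of genes, where chance gives 10%. The count was 1554 without R2 replicate 4. Lower genes outnumbered higher ones after quantile normalization again (1164 higher, 1229 lower), without R1 replicate 5 (989 and 1001) and without R2 replicate 2 (822 and 831).

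The comparison of R3 with R1 asks the same of the GFP-positive papilla population. Ugt8a was 38.1-fold higher in R3 (log2 change 5.25, standard error 0.28, n = 3 per gate, adjusted p = 4.2e-06), against a level of 3.02 in R1 that lies under the background guide. Rspo2 was 37.8-fold higher, the testican gene Spock1 28.5-fold, Sox2ot 23.3-fold and Scube3, a secreted signalling protein gene, 20.2-fold. Adgrb3, the coagulation factor gene F5 and Slco4c1 were 19.4-fold, 19.3-fold and 18-fold higher. C1qtnf3, a secreted protein gene of mesenchyme, was 30.6-fold lower (log2 change -4.94, standard error 0.43, adjusted p = 6.75e-05). Cd69 was 27.7-fold lower, Krt27 27.3-fold, Krt25 21.8-fold and Fgfr4 21.3-fold, and the mast cell genes Mcpt4, Cma1 and Mrgprb1 were 21-fold, 19.1-fold and 17.5-fold lower.

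The beta-actin 3' to 5' difference lay higher in R3 than in R1 (mean 0.15 against 0.05), beside each gene group of this comparison. That of Gapdh averaged 2.84 in R3 and 2.85 in R1, with overlapping arrays. Of 31 dermal papilla genes 25 rose in R3 (27 higher and 2 lower adjusted over the list alone), with a median of 1.51 (camera adjusted p = 3.86e-20, and 0.00268 with an estimated correlation). Corin was 16.2-fold, Inhba 8.91-fold and Rspo3 3.45-fold higher. Glial genes rose in 6 of 11 cases (9 adjusted over the list alone; camera adjusted p = 7.6e-07, and 0.0299 with an estimated correlation), with Mbp 17.8-fold, Cdh19 8.85-fold and S100b 5.79-fold higher. Cell cycle genes fell in 21 of 30 cases (25 adjusted over the list alone), with a median of -0.87 (camera adjusted p = 6.71e-12, and 0.0465 with an estimated correlation); the replication helicase genes Mcm3 and Mcm2 were 2.71-fold and 2.44-fold lower. Fibroblast and matrix genes fell in 17 of 28 cases and 1 rose (22 and 1 adjusted over the list alone; camera adjusted p = 2.15e-09, and 0.0191 with an estimated correlation), with Lum 5.67-fold and Dcn 4.26-fold lower.

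Keratinocyte genes fell in 18 of 22 cases (18 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.04e-13, but adjusted p = 0.07 with an estimated correlation), with Krt14 9.65-fold and Krt5 8.09-fold lower. Leukocyte genes fell in 10 of 23 cases (11 adjusted over the list alone; camera adjusted p = 0.000446, but adjusted p = 0.14 with an estimated correlation). Endothelial genes were lower in 8 of 16 cases and higher in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.00586, but adjusted p = 0.151 with an estimated correlation). The endothelial call was also lost among genes above the median gene (camera adjusted p = 0.428). Esam was 4.40-fold and Emcn 3.63-fold lower while Flt1 was 3.44-fold higher. The count of lower endothelial genes was 5 without R1 replicate 4, and that of higher ones was 1 without R1 replicate 2, R1 replicate 4, R3 replicate 4 or R3 replicate 5. BMP genes rose in 12 of 32 cases and 1 fell (14 and 2 adjusted over the list alone; camera adjusted p = 6.77e-05, but adjusted p = 0.121 with an estimated correlation), with Bmp7 5.84-fold and Bmp6 3.10-fold higher and the antagonist Grem1 4.30-fold lower.

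Adipocyte, melanocyte, skeletal muscle and pericyte genes were lower as sets (adjusted p = 0.00105, 0.00624, 0.00694 and 0.0219, and with an estimated correlation adjusted p = 0.107, 0.246, 0.107 and 0.14), with Lpl 5.37-fold, Kit 5.70-fold, Myog 6.23-fold and Kcnj8 11-fold lower. The pericyte and melanocyte calls were also lost among genes above the median gene (camera adjusted p = 0.163 and 0.0505). Immediate early and stress genes were higher as a set (adjusted p = 0.0219, and adjusted p = 0.151 with an estimated correlation). That call was lost without R1 replicate 4 (adjusted p = 0.052) or R3 replicate 2 (adjusted p = 0.0657). It was also lost with the mouse as a random effect and cameraPR (adjusted p = 0.0705) and with the mean of all probe sets of a gene (adjusted p = 0.0523). The range was 0.00296 to 0.151 over its alternatives. The 11 remaining lists had adjusted p from 0.178 to 0.918. Of these, Notch genes were called with the mouse as a random effect and cameraPR (adjusted p = 0.0115, range 0.0115 to 0.463). HOX genes were called among genes above the median gene (adjusted p = 0.0489, range 0.0489 to 0.848). Among their genes, Hey2 was 9.47-fold, Ltbp1 4.47-fold and Pappa2 7.67-fold higher, and Inhbb 10.2-fold and Cdon 8.41-fold lower. In all, limma called 3406 genes between R3 and R1, 1438 higher and 1968 lower in R3, of which 3399 had the same sign in all 3 mice. The arrays did not overlap for 34.4% of genes, where chance gives 10%.

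**Figure D3:**
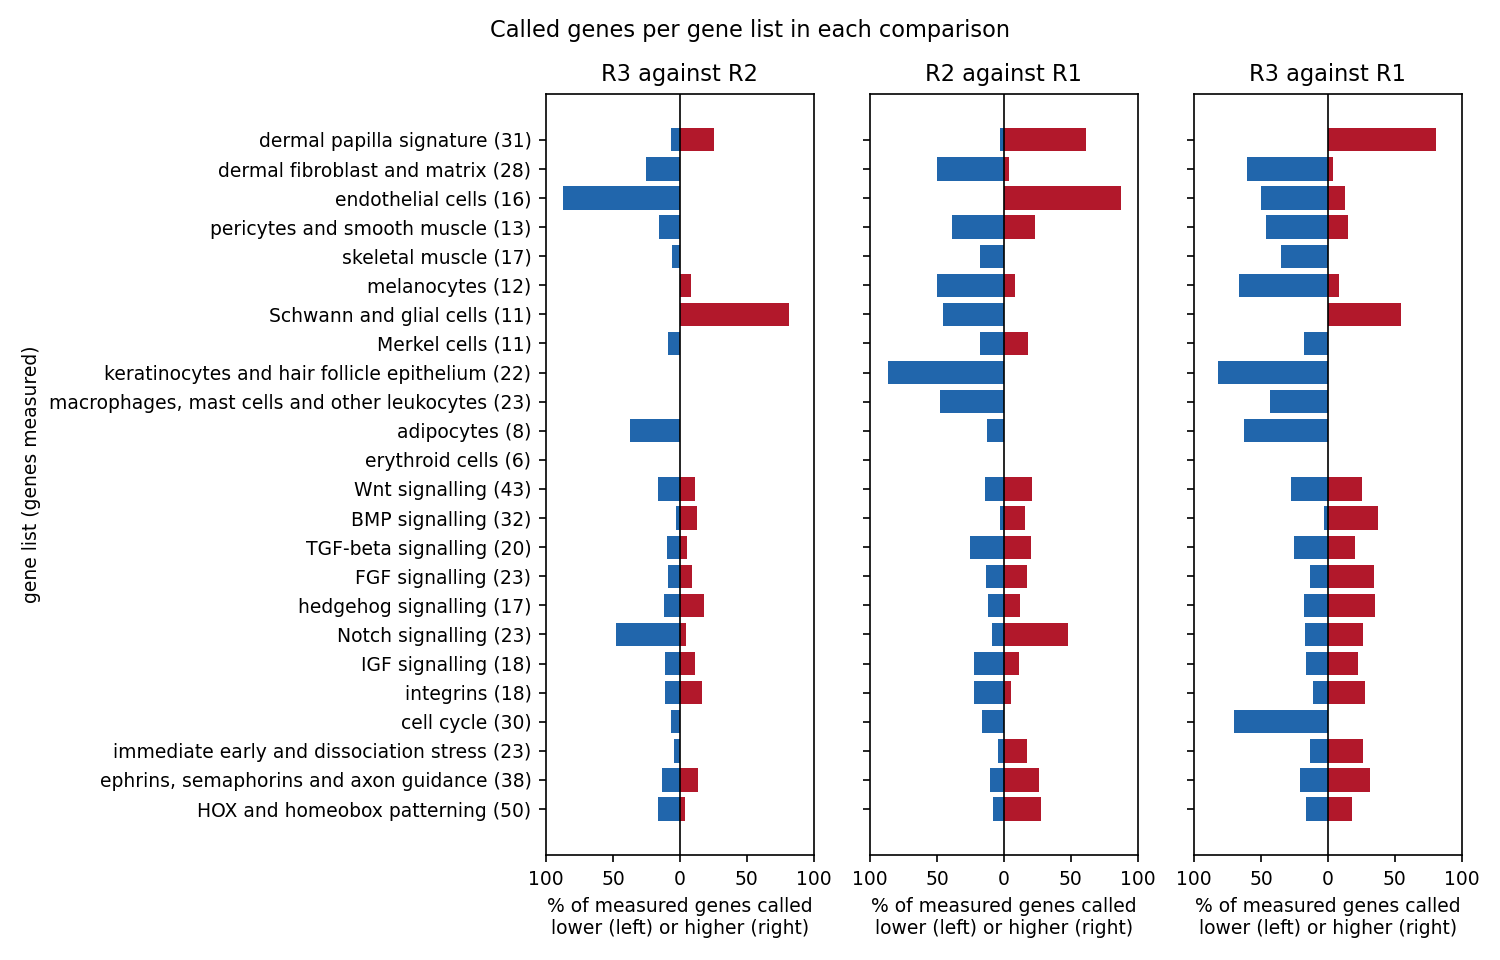
Percent of the measured genes of each of 24 gene lists called lower (left, blue) or higher (right, red) by limma (x axis, %) in the 3 comparisons, with the number of measured genes beside each list (y axis). Endothelial genes lie to the left in R3 against R2 (14 of 16) and to the right in R2 against R1 (14 of 16), and glial genes to the right in R3 against R2 (9 of 11).

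Many genes set both papilla populations apart from R1. In both comparisons 746 genes were called higher, among them Corin, Inhba, Spock1 and Sox2ot, where independent lists of these lengths would share 99.1. In both, 864 genes were called lower, among them Krt25, Krt27 and Cd69, where independent lists would share 121.3. In R1, Krt25 and Krt27 stood at 11.04 and 10.60, and the mast cell gene Cma1 at 12.09. R1 thus held RNA of epithelial and mast cells, and what its cell mix adds to the shared calls was not tested. Of the 746, 56 were higher and 33 lower in R3 than in R2, and of the 864, 8 were higher and 62 lower. The log2 changes against R1 correlated across genes at 0.719. Simulations without changes, in which both groups were set against a shared simulated control, gave 0.503 (mean of 20 simulations). That simulated value reflects the shared control and was not measured from the real R1 arrays. The covariance of the log2 changes against R1 was 0.268, against 0.023 in the simulations, a difference of 0.245. The sign was shared by 73.7% of genes, against 66.7% in the simulations. In all, 1671 genes were called in both comparisons; simulated groups without changes gave 0, which says nothing of lists that hold real changes. The 3 R1 arrays are too few to be split, so part of the excess of shared calls over independent lists may come from the shared R1 arrays.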

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

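All alternatives were planned. Asking for at least a 2-fold change left 509 genes in R3 against R2, 1083 in R2 against R1 and 1476 in R3 against R1, since it drops the smaller changes. With an estimated correlation, 5, 6 and 4 gene lists were called in place of 10, 14 and 13. Leaving out 1 array, which also lowers the number of arrays, gave 582 to 813 genes in R3 against R2, 1554 to 1990 in R2 against R1 and 2519 to 3009 in R3 against R1. The mouse as a fixed block gave 881, 2431 and 3494 genes and kept 759 of the 915 calls between R3 and R2. Among the lists it changed only the call of the BMP list in R3 against R2. With the mouse as a random effect, lists were tested with cameraPR in place of camera. Changed list calls in that setting therefore cannot be credited to the mouse alone. The other counts of genes and of lists stayed within 1.5 times those reported. The changes of Prom1 and Sox2 stayed called in the same direction in all 78 values computed. For the called results of named genes and of the up to 4 lowest-p members of each list, 3666 of 3788 values stayed called in the same direction. Of the others, 122 were no longer called and 0 reversed. These genes are among the strongest calls. Of all 915 calls between R3 and R2, 546 (without R2 replicate 4) to 670 (without R3 replicate 5) stayed called with 1 array left out. With the mean of all probe sets of a gene, 2 of them changed sign, as did 5 calls in R2 against R1 and 14 in R3 against R1. Of the values for single lists, 1020 stayed on the same side of the threshold, 37 lost the call and 14 gained it. Signals under the background guide limit the folds of dim genes.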

Other observations

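The second glial and endothelial lists and the splits were fixed before the values they test were seen, but after the glial and endothelial patterns; the distal position list, the tests of transcription in the papilla cells themselves and the test of Sox2 carry-over were chosen after the results were seen. Against R1, 61 genes were called in opposite directions in R2 and R3. Of these, 21 were higher in R3 and lower in R2, among them the myelin genes Cnp (log2 change 1.60 in R3 and -2.21 in R2) and Bcas1 (3.50 and -1.71), and Chl1 (3.49 and -0.72). The other 40 were higher in R2 and lower in R3, among them Emcn (2.01 in R2 and -1.86 in R3), Adgrf5 (1.96 and -2.11) and the endothelial cadherin gene Cdh5 (1.38 and -1.57). These genes were picked after their values were seen.

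In a list of 16 genes of distal limb and posterior position, 7 of which are also in a list fixed earlier, 3 of 14 measured genes were lower in R3 than in R2, Hoxd10, Hoxd13 and Tbx4 (log2 change -2.21, standard error 0.43, adjusted p = 0.0185). The camera p was 3.08e-05, and 0.0784 with an estimated correlation. The list was written after the falls of Hoxd13 and Hoxd10 had been seen and holds both, so this p is no independent test. The count was 1 without R2 replicate 2, R2 replicate 4 or R3 replicate 4, 2 without R3 replicate 2 or R3 replicate 5, and 6 without R2 replicate 5. In R2 of mice 2, 4 and 5, Hoxd13 stood at 9.34, 9.90 and 6.83, Hoxd11 at 7.65, 7.18 and 5.36, Tbx4 at 7.91, 7.67 and 6.06, and Hoxd10 at 8.37, 7.93 and 7.79.

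Glial transcripts were higher in R3 than in R2. One candidate explanation is Schwann or glial cells sorted with the GFP+CD133+ gate. In a second list of 30 glial genes, none in a list fixed earlier, 74.1% of the 27 measured were called higher in R3 (median log2 change 1.60), as such cells would bring; of its most abundant members in R3, Cnp, Plekhb1, Pmp22 and Apod were 14-fold, 13.7-fold, 2.01-fold and 2.01-fold higher, while Matn2 stood at 11.12 in R3 and 10.86 in R2 (adjusted p = 0.708), and Apod was also 3.59-fold higher in R2 than in R1. The other is transcription of glial genes in the papilla cells themselves, for which the median change of the fixed list, 1.97, would look alike, so the 2 cannot be told apart from values per gate. A gate on GFP and CD133 removes glial cells only where they lack either.

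Endothelial transcripts were higher in R2 than in R3. One candidate explanation is endothelial cells sorted with the GFP-CD133+ gate. In a second list of 25 endothelial genes, none in a list fixed earlier, 76% were called lower in R3 (median log2 change -1.50), among them the abundant Erg (4.68-fold), Ptprb (4.64-fold), Bcl6b (8.36-fold) and Cyyr1 (11-fold), while the equally abundant Tmem204 stood at 10.20 in R2 and 9.38 in R3 (adjusted p = 0.125). The other is an endothelial programme in the papilla cells of R2, for which the median change of the fixed list, -2.22, would look alike, so the 2 cannot be told apart from values per gate. A gate on CD133 removes endothelial cells only where they lack it.

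Sox2 RNA in R2 stood above R1, at 8.36% of its level in R3 (12.7%, 5.69% and 8.06% in mice 2, 4 and 5). A candidate explanation is cells of the GFP+CD133+ gate, with the composition of R3, carried over into R2. Mbp, the single glial gene that met the condition of the test, stood in R2 at 1.53% of its R3 level (2.43%, 1.86% and 0.789% by mouse). The R2 level of Mbp was 5.92, and those of Mal and Bcas1, 31-fold and 37.1-fold higher in R3, were 5.50 and 4.75. These levels lie in or under the range of the background guide, so such shares are upper limits. The share of Mbp lay under that of Sox2 in each mouse. Since the test rests on 1 gene, carry-over and Sox2 transcription in R2 cells cannot be told apart, and the latter was not tested.

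With 3 arrays against 3 there are 10 splits, so the share of splits with as many called genes cannot go under 0.1. Each split was fitted with all 9 arrays, the gate outside the comparison kept as it was. In each comparison 1 of the 10 splits, the real one, gave as many: 915, 2375 and 3406 genes, with 0 as the highest of the other splits. Of these others, 3 part the arrays of all 3 mice as the real split does, and 6 part those of 1 mouse. Among splits that part all 3 mice the lowest possible share is higher still. Every other split puts arrays of both gates into each group, so the gate differences widen the spread there. Few calls were therefore likely in advance, and the 0 does not show what chance would give among alike arrays.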
